A study of Mus musculus with 6 samples.

How the data were processed

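RNA sequencing was compared between primary chondrocytes of neonatal mice lacking the adenosine receptor encoded by Adora2a (A2ARKO) and wild-type mice (WT). Per the labels' protocols, each library holds RNA from trypsinized cells pooled over a whole litter, with 3 litters per genotype, and sequencing was on an Illumina HiSeq 4000. Both genotypes are labelled as C57BL/6 and as kept in the same facility. A replicate is therefore a pool of litter mates, and p-values measure the spread between litters. No culture, harvest or sequencing batch is given in the sources used here.

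The authors deposited 1 table of FPKM (fragments per kilobase of gene per M fragments, M for mega) with 47480 genes in rows and 6 libraries in columns, rounded to 2 decimals. Per the submitters' processing notes, HTSeq and the genome build mm10 were used. The aligner, the tool versions, the annotation, the gene lengths and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and values of near-identical copies such as Saa1 and Saa2 or of genes with many processed pseudogenes are uncertain. All 6 columns were used, each assigned to its sample by its title. FPKM divide each gene by its length and each library by a total, so they carry no count error of their own, and a very abundant transcript can lower the values of the others. The column sums ranged from 231094 to 300779. The median ratio of each library to the geometric mean of the 6 lay between 0.993 and 1.008 over the tested genes, so the typical gene was already level between libraries.

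Depth was estimated from the low values. Among annotated genes of at most 150 nt, FPKM times length took steps of a fixed size in each library, and 99.0% or more of the values up to 10 reads were whole numbers of reads within a tolerance of 0.1 read. In simulated values with a known step, the step was recovered within 0.19%. The steps correspond to totals of 41.8 to 58.0 M reads (M, mega) behind the scaling of each library. Multiplying FPKM by exon length, dividing by the step and summing over genes gave 51.5 to 64.7 M reads, and why these exceed the former was not tested. Exon lengths came from GENCODE release M21 on GRCm38, the assembly named mm10, and 45114 of the 47480 rows matched 1 annotated gene by name. The annotation behind the deposited values may differ, so these reads are approximate and enter only the comparison of libraries with sampling noise and an added alternative. No pair of libraries of the same genotype differed by as little as sampling noise, so all 6 were counted as separate replicates. The closest such pair, A2ARKO replicates 2 and 3, had a median chi-square 11.5 times that of sampling noise.

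Genes with an FPKM of 1 or more in at least 3 of the 6 libraries were tested, which kept 11595 genes. Differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), two-sided, without a replicate block, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p below 0.05. Fold changes are A2ARKO minus WT on the log2(FPKM + 1) scale, which understates the change of low genes, and for Adora2a the ratio of mean FPKM is given beside it. Adora2a was in addition tested with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Simulated data used each gene's mean over the 6 libraries and 1 pooled spread for both groups, and genes were drawn independently. In them, 50 genes each were changed by 0.5, 1, 2 or 4 log2 units, all with a mean log2(FPKM + 1) above log2(6). The same fit over 11595 genes recovered 26%, 64%, 92% and 98% of them, with 6 false calls among 11395 unchanged genes. In the real libraries the median SD was 0.192 in WT and 0.097 in A2ARKO. The shares do not cover such unequal spreads, lower genes or correlation between genes.

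Before the data were examined, 39 gene lists were written down from general knowledge of cartilage, osteoarthritis, adenosine signalling, stress and metabolic pathways, and of other cell types that a chondrocyte preparation can hold. The 34 lists with 5 or more tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Camera with a correlation estimated for each list and fry, which tests a list without comparing it with other genes, were run beside it. The number of members past the threshold is given over all genes and adjusted over the list alone. The genes named follow a rule fixed at the same time: Adora2a; the 10 genes with the largest rise and the 10 with the largest fall among called genes with no overlap between the groups; and from each list up to 4 called members with the largest change or, where none was called, up to 2 with the smallest unadjusted p. Predicted genes (Gm and Rik names) were counted and gave way to the next gene. Some genes that the rule takes are not reported here.

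Principal components were computed from the tested genes, centred per gene. Genes within 10 Mb of Adora2a were compared with all other tested genes by a two-sided Fisher's exact test, using the 11244 tested genes with an annotated position. Alternatives fixed before the data were examined covered the pseudocount (0.1 and 5), the filter, the scaling between libraries, the variance model, a replicate block, leaving out each library, the threshold and the window. Alternatives for tables of raw counts did not apply to FPKM. Chosen after seeing the data were a limma-voom fit on the approximate reads, the counts of list members with each library left out, a fit without muscle and leukocyte genes and WT replicate 2, and 5 further gene lists, which were picked from these libraries and are not independent evidence. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the depth estimate and the figures. Pathway, transcription factor and network databases were not used here.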

Results

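The transcriptome of primary chondrocytes, the cells of cartilage, from neonatal mice was compared between A2ARKO animals, which lack the adenosine receptor encoded by Adora2a, and WT animals, with 3 litter pools in each group. The comparison was set up to characterize drivers of osteoarthritis, the degenerative joint disease in which cartilage is lost. Values are FPKM as mean ± SD over 3 libraries. The depth estimated from the steps between low values was 41.8, 49.8 and 52.7 M reads (M, mega) in WT replicates 1, 2 and 3 and 51.6, 58.0 and 52.6 M reads in A2ARKO replicates 1, 2 and 3. Reads summed over the genes with annotated exon lengths came to 59.4, 51.5 and 53.5 and to 56.6, 64.7 and 63.9 M, so WT replicate 1 ranked lowest by the former and highest of WT by the latter. Where values are given for each library left out in turn, the order is WT replicates 1, 2 and 3, then A2ARKO replicates 1, 2 and 3.

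Adora2a, the gene of the deleted receptor (mm10 chromosome 10, 75316877 to 75334784, plus strand), was low in every A2ARKO library. Its FPKM was 9.36, 7.31 and 3.46 in the WT libraries and 0.41, 0.54 and 0.66 in the A2ARKO libraries. The mean fell from 6.71 ± 2.995 to 0.537 ± 0.125 FPKM (SD, n = 3), 12.5-fold lower, and the log2 fold change was -2.245 with a standard error of 0.31 (limma adjusted p = 0.0203). The two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Without WT replicate 2 or without A2ARKO replicate 1, 2 or 3 the limma adjusted p was 0.0582, 0.0824, 0.0955 and 0.0864, and the log2 fold change lay between -2.60 and -1.99 whichever library was left out. The deleted part of the gene is not given in the sources used here, so reads in the A2ARKO libraries can lie outside it.

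Saa3, Lcn2, Saa2, Saa1 and Cxcl1, of the list of inflammatory mediators, were among the 10 largest rises in A2ARKO chondrocytes. First was Chil1, which encodes a secreted chitinase-like protein, from 2.65 ± 1.74 to 2021 ± 1131 FPKM (SD, n = 3) at a log2 fold change of 9.08 (limma adjusted p = 0.00278). It was followed by Saa3, a serum amyloid A protein (130.0 ± 194 to 13339 ± 6239 FPKM), the iron-sequestering lipocalin Lcn2 (18.9 ± 10.9 to 2676 ± 1215 FPKM) and the matrix protease gene Mmp3, encoding stromelysin (29.7 ± 37.5 to 2286 ± 1488 FPKM). Saa2, Saa1, the neutrophil chemokine gene Cxcl1, the pantetheinase gene Vnn1, U90926 and Vnn3 completed the 10 largest rises, at log2 fold changes of 6.06, 5.84, 5.60, 5.15, 5.08 and 4.93. Saa3 alone held 3.32%, 3.9% and 6.81% of all FPKM in the A2ARKO libraries. Saa1 and Saa2 are near-identical copies, so reads may be split between them. Saa3 did not pass without WT replicate 3 (adjusted p = 0.0603) or without A2ARKO replicates 1, 2 and 3 (0.1065, 0.1303 and 0.134). Its log2 fold changes in these fits were 7.974, 8.438, 8.315 and 7.84. Mmp3 did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.0714, 0.0941 and 0.0909).

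**Figure D1:**
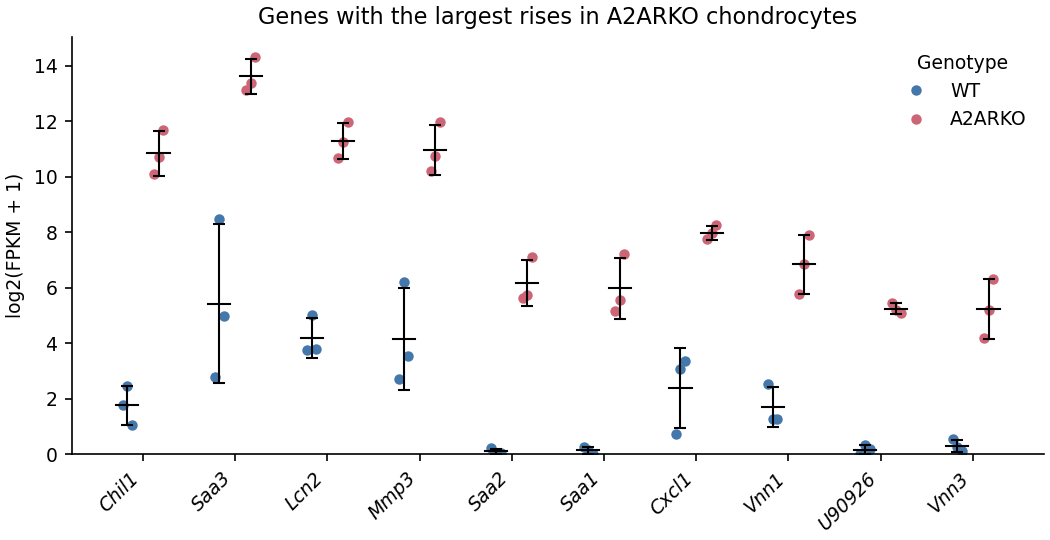
Level of the 10 genes with the largest rises, as log2(FPKM + 1) in each library; points are libraries, and black bars give the mean ± SD of 3 libraries per genotype. All 3 A2ARKO values lie above all 3 WT values for each gene, and Saa3 ranges within WT from 5.93 to 354 FPKM.

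Aspn, which encodes the small leucine-rich proteoglycan asporin, had the largest fall among called genes other than predicted ones, from 172 ± 89.7 to 7.43 ± 1.93 FPKM (SD, n = 3) at a log2 fold change of -4.25 (limma adjusted p = 0.00789). Igfbp5, an insulin-like growth factor binding protein, fell from 238 ± 79.75 to 24.3 ± 11.2 FPKM. Eln, encoding elastin, and Fbn2, encoding the microfibril protein fibrillin-2, fell at log2 fold changes of -2.95 and -2.08. The homeobox gene Meox1, the R-spondin receptor gene Lgr5, Cthrc1, Nrep and the matrix gene Dpt fell at -2.84, -2.71, -2.60, -2.40 and -2.22, and Adora2a itself ranked among the 10. Aspn did not pass without A2ARKO replicate 2 (adjusted p = 0.0521). Igfbp5 did not pass without WT replicate 2 (adjusted p = 0.0569) or without A2ARKO replicates 2 and 3 (0.0649 and 0.0749). Eln did not pass without WT replicate 2 (adjusted p = 0.0682) or without A2ARKO replicates 1, 2 and 3 (0.0983, 0.123 and 0.119).

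**Figure D2:**
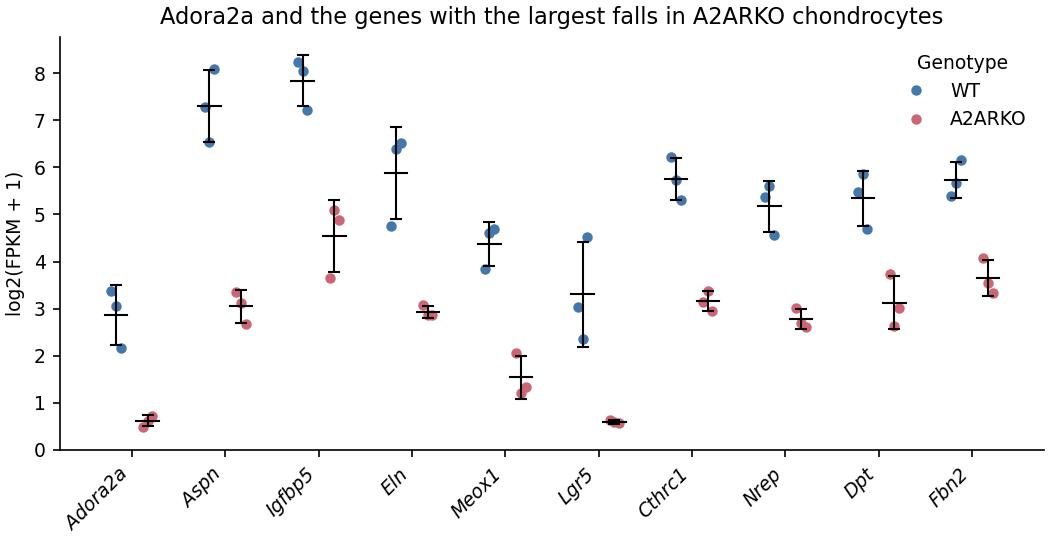
Level of Adora2a and of the other genes among the 10 largest falls, as log2(FPKM + 1) in each library; points are libraries, and black bars give the mean ± SD of 3 libraries per genotype. Aspn averages 172 FPKM in WT and 7.43 FPKM in A2ARKO.

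Across the transcriptome, limma called 589 of 11595 tested genes (adjusted p below 0.05), 384 higher and 205 lower in A2ARKO, and 253 of them differed by 1 log2 unit or more. The groups did not overlap for 3813 genes, or 32.9%, where 10% is the average over all splits of the libraries. Genes vary together, so 1 split can lie far from that average, and the difference was not tested. The share of higher calls, 65.2%, was 51.1% after rescaling the libraries to the same sum (348 genes), 50.5% when ribosomal protein, haemoglobin and unnamed genes were also left out, and 53.8% after quantile normalization. The number called with each library left out in turn was 900, 300, 852, 120, 50 and 75. These fits have fewer libraries. In each of them 100% of the 589 genes kept an unadjusted limma p below 0.05, on data shared with the main fit. Of the largest rises and falls, Chil1, Lcn2, Saa2, Saa1, U90926 and Cthrc1 passed whichever library was left out. The others lost the call in at least 1 of these 6 fits. Their groups do not overlap, so leaving out a library could not change their sign. Of the 79 called genes that the rule for named genes takes other than Adora2a, 66, 46, 62, 27, 9 and 18 passed with each library left out in turn. With all libraries, 34 of the 79 passed with no filter, 54 after rescaling to the same sum and 1 with a replicate block.

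Inflammatory mediators rose as a list: 16 of 26 tested members rose, 0 fell and 10 did not pass, and 20 passed adjusted over the list alone (median log2 fold change 2.07; camera adjusted p = 1.73e-15; adjusted p = 0.375 with an estimated correlation). Besides Saa3, Lcn2, Saa2 and Saa1, the members that rose include Cxcl1, from 5.71 ± 4.47 to 254 ± 45.9 FPKM (SD, n = 3). Cxcl1 did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.0641, 0.0797 and 0.0749). A total of 19, 18, 12, 9, 8 and 8 members rose with each library left out in turn. Lcn2, Saa2 and Saa1 passed in all 6 of these fits. Of the list's 33 members, 11 reached 1 FPKM in every library, and the filter admits members such as Saa1 and Saa2 through the A2ARKO libraries alone. Tnf and Il1b, named after their values were seen, were below the filter. They averaged 1.65 ± 2.47 and 0.0867 ± 0.150 FPKM in WT and 0.53 ± 0.327 and 0.147 ± 0.110 FPKM in A2ARKO. Markers of macrophages and other leukocytes had a median log2 fold change of -1.89 with 0 of 11 called, and the macrophage lysozyme gene Lyz2 read 128, 1434 and 104 FPKM in the WT libraries and 31.02, 15.5 and 11.6 in the A2ARKO libraries.

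Genes of the NF-kappaB pathway, a main signalling route of inflammation, rose as a list (camera adjusted p = 3.21e-06; adjusted p = 0.415 with an estimated correlation). Of 20 tested members 4 rose and 16 did not pass, with 9 adjusted over the list alone. These were Nfkbiz (3.25 ± 1.19 to 24.2 ± 6.73 FPKM), the kinase genes Ripk2 and Map3k8, and Nfkb1, at log2 fold changes of 2.57, 1.04, 1.02 and 0.44. Nfkbiz did not pass without A2ARKO replicates 2 and 3 (adjusted p of 0.0658 and 0.0547). Of the list, 5, 7, 2, 2, 0 and 0 members rose with each library left out in turn. Interferon-stimulated genes lay above 0 in 28 of 28 tested members (27 after rescaling to the same sum) and rose as a list (camera adjusted p = 2.30e-10; adjusted p = 0.417 with an estimated correlation). Over all genes, Irf7 and Ifih1 rose at log2 fold changes of 2.09 and 1.29 and 26 did not pass, with 23 adjusted over the list alone. Both lost the call whichever library was left out, with adjusted p between 0.0607 and 0.151, and 1, 0, 1, 0, 1 and 0 members rose with each left out in turn.

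Complement genes, which encode serum proteins of innate immunity, rose as a list (camera adjusted p = 0.0309; adjusted p = 0.417 with an estimated correlation): 5 of 15 tested members rose and 10 did not pass, and adjusted over the list alone 10 rose and 4 fell. C3 rose from 21.45 ± 21.6 to 448 ± 172 FPKM (SD, n = 3), and Cfb, C1ra and Masp1 rose at log2 fold changes of 1.82, 1.30 and 0.96. The macrophage-expressed members C1qa, C1qb and C1qc, named after their values were seen, had log2 fold changes of -3.22, -3.90 and -2.98 and did not pass. The list's adjusted p was 0.0556 without WT replicate 1 and 0.1003 without WT replicate 3, and 4, 2, 5, 0, 0 and 1 members rose and 1, 0, 0, 0, 0 and 0 fell with each library left out in turn. Protease inhibitors rose as a list (camera adjusted p = 0.0458; adjusted p = 0.463 with an estimated correlation), with 3 of 12 members higher, 9 not past the test and 6 adjusted over the list alone. They include Serpina3n and Timp1, an inhibitor of matrix metalloproteases (269 ± 44.2 to 899 ± 104 FPKM). The adjusted p of that list was 0.114 without WT replicate 2 and 0.177 without WT replicate 3, and 4, 2, 3, 1, 0 and 1 members rose with each library left out. Of 24 matrix proteases, Mmp3 rose and 23 did not pass (median -0.29; camera adjusted p = 0.139; adjusted over the list alone, 2 rose and 3 fell), and the list was called lower without WT replicate 1 (adjusted p = 0.0395) and without A2ARKO replicate 1 (0.02975), with 2, 1, 2, 0, 0 and 0 members higher and 0, 0, 3, 0, 0 and 0 lower with each library left out. C3 did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.0749, 0.104 and 0.103). Timp1 did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.0576, 0.0696 and 0.07202).

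Glycolysis genes rose as a list (median log2 fold change 0.83; camera adjusted p = 9.99e-08; adjusted p = 0.417 with an estimated correlation), with 5 of 20 members higher, 15 not past the test and 14 adjusted over the list alone. The lactate dehydrogenase gene Ldha rose from 194 ± 29.5 to 500.2 ± 108 FPKM (SD, n = 3), and Pfkl, Pkm and the hexokinase gene Hk1 rose at log2 fold changes of 1.24, 1.07 and 0.88. Pfkl lies within 5 Mb of Adora2a and Hk1 within 20 Mb of it. Of the list, 6, 1, 2, 0, 0 and 0 members rose with each library left out in turn. Cholesterol synthesis genes fell as a list (median -0.32; camera adjusted p = 4.46e-05; adjusted p = 0.375 with an estimated correlation). Hmgcs1, Cyp51 and Mvd of 19 members fell, 16 did not pass, and 9 passed adjusted over the list alone. Hmgcs1, encoding an early enzyme of the pathway, fell from 91.1 ± 9.74 to 57.9 ± 1.64 FPKM (SD, n = 3), and 3, 2, 4, 0, 0 and 0 members fell with each library left out. None of 37 nuclear-encoded genes of oxidative phosphorylation passed by limma (median 0.015, and -0.10 after rescaling to the same sum; camera adjusted p = 0.953; 0 adjusted over the list alone, 1 at an unadjusted p below 0.05), and Ndufa1 and Cox7a2, with the smallest p, had log2 fold changes of 0.33 and 0.22. The 13 mitochondrially encoded genes were not analysed here. Ldha did not pass without WT replicates 2 and 3 (adjusted p of 0.0553 and 0.0529) or without A2ARKO replicates 1, 2 and 3 (0.0601, 0.143 and 0.119). Hmgcs1 did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.1203, 0.175 and 0.145).

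Antioxidant genes rose as a list (camera adjusted p = 4.46e-05; adjusted p = 0.375 with an estimated correlation): 5 of 26 members rose, 21 did not pass, and adjusted over the list alone 11 rose and 1 fell. The superoxide dismutase genes Sod2 (15.5 ± 7.63 to 58.8 ± 6.08 FPKM) and Sod3, the glutathione synthesis gene Gclc and Prdx5 rose at log2 fold changes of 1.95, 1.22, 1.29 and 0.88, and 6, 5, 5, 1, 0 and 0 members rose and 0, 0, 1, 0, 0 and 0 fell with each library left out in turn. Genes of p53, senescence and apoptosis rose as a list (camera adjusted p = 0.00156; adjusted p = 0.375 with an estimated correlation), with 4 of 25 members higher, 21 not past the test and 8 adjusted over the list alone. These were the death receptor gene Fas, the p53 inhibitor gene Mdm2, Pmaip1 and the cell cycle inhibitor gene Cdkn1a (143 ± 2.86 to 236 ± 21.5 FPKM), and 5, 2, 6, 2, 0 and 1 members rose and 0, 0, 1, 0, 0 and 0 fell with each library left out. Sod2 did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.102, 0.1125 and 0.119). Cdkn1a did not pass without WT replicates 2 and 3 (adjusted p of 0.0691 and 0.0543) or without A2ARKO replicates 1, 2 and 3 (0.0836, 0.173 and 0.157). Cell cycle genes lay above 0 in 32 of 32 members and rose as a list (camera adjusted p = 1.83e-10; adjusted p = 0.417 with an estimated correlation). Of these 5 rose and 27 did not pass, with 14 adjusted over the list alone; Rrm2, Mcm5, Ccne1 and Cdc6 rose at 2.13, 1.02, 0.98 and 0.85. Members that rose with each library left out numbered 7, 1, 20, 0, 0 and 0.

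Immediate early and heat shock genes, which respond to acute stimuli, rose as a list (camera adjusted p = 0.0126; adjusted p = 0.375 with an estimated correlation). Ier3, Btg2 and Ier5 were among the 4 of 22 members that rose, at log2 fold changes of 2.35, 1.08 and 0.93, the transcription factor gene Klf2 fell at -1.09, and 17 did not pass; adjusted over the list alone 9 rose and 2 fell. Ier3 passed whichever library was left out, and 6, 3, 4, 2, 1 and 2 members rose and 1, 1, 1, 0, 0 and 1 fell with each left out in turn. Of 29 genes of FoxO signalling and autophagy, Sesn1 fell at -0.69 and 28 did not pass (camera adjusted p = 0.0789; 1 fell adjusted over the list alone), and the list was called lower without WT replicate 3 (adjusted p = 0.0472); 2, 1, 1, 0, 0 and 0 members fell with each library left out. Of 23 genes of the unfolded protein response, Trib3 fell from 54.4 ± 21.2 to 12.6 ± 1.25 FPKM (SD, n = 3) and 22 did not pass (camera adjusted p = 0.299; adjusted over the list alone, 2 rose and 4 fell), with 2, 0, 0, 0, 0 and 0 higher and 3, 0, 3, 0, 0 and 0 lower with each library left out. Trib3 did not pass without WT replicate 2 (adjusted p = 0.0546) or without A2ARKO replicates 1, 2 and 3 (0.0776, 0.0993 and 0.0852). Sesn1 did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.0624, 0.0808 and 0.0802).

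Among 24 genes for adenosine and extracellular nucleotide handling, 3 rose and 21 did not pass (5 rose adjusted over the list alone; camera adjusted p = 0.06895). The AMP deaminase genes Ampd3 and Ampd2 rose at log2 fold changes of 2.05 and 0.51, Ampd3 from 4.44 ± 0.127 to 21.9 ± 5.105 FPKM (SD, n = 3). The adenosine receptor gene Adora1 rose at a log2 fold change of 1.07 from a low level, 0.107 ± 0.0551 to 1.36 ± 0.5804 FPKM. It lies on mm10 chromosome 1 (134199223 to 134235431, minus strand), near Chil1 (134182176 to 134190181, plus strand), which averaged 2021 FPKM in A2ARKO. The strand setting is not given, and whether reads from Chil1 were counted for Adora1 was not tested. Ampd3 passed whichever library was left out, 5, 2, 2, 1, 1 and 1 members rose with each left out in turn, and the list was called higher without WT replicate 2 (adjusted p = 0.0316) and without A2ARKO replicate 1 (0.02975). Adora1 did not pass without WT replicates 2 and 3 (adjusted p of 0.0767 and 0.0576) or without A2ARKO replicates 1, 2 and 3 (0.0882, 0.1125 and 0.0785). None of 14 cAMP-responsive genes passed over all genes by limma (camera adjusted p = 0.302; 6 at an unadjusted p below 0.05; adjusted over the list alone, 2 rose and 2 fell). The smallest p values among them were those of Nr4a1 and Nfil3, at log2 fold changes of -0.97 and 0.80 with limma adjusted p of 0.0581 and 0.0837. Without WT replicate 1, 3 of them rose and 2 fell.

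Cartilage matrix genes spanned a wide range among the WT litters. Col2a1, encoding the main collagen of cartilage and named after its values were seen, read 18662, 808 and 185 FPKM in the WT libraries and 1363, 2938 and 3887 in the A2ARKO libraries. The median level of the list, as log2(FPKM + 1), was 7.63, 3.25 and 2.20 in WT replicates 1, 2 and 3 and 4.79, 5.63 and 6.39 in A2ARKO replicates 1, 2 and 3. Of 24 members, Cilp, encoding cartilage intermediate layer protein, fell from 3.79 ± 2.29 to 0.113 ± 0.0666 FPKM (SD, n = 3), 23 did not pass, and adjusted over the list alone 1 fell (median 0.90; camera adjusted p = 0.613). Without WT replicate 1 the list was higher in A2ARKO (6 members rose, 1 fell, median 2.03, camera adjusted p = 2.66e-06), and without WT replicate 3 its median was -0.34. None of 15 chondrocyte regulators passed limma (camera adjusted p = 0.386; 1 at an unadjusted p below 0.05) and none of 14 genes of hypertrophy and mineralization (adjusted p = 0.953; 4 at an unadjusted p below 0.05), with 0 adjusted over the list alone in both; the log2 fold changes of Gdf5, Arid5b, Mef2c and Vegfa were 1.55, 0.64, -1.37 and 0.45. Without WT replicate 1 both lists were called higher, at adjusted p of 9.19e-04 and 0.00947, with 1 and 3 members higher, and when WT replicate 3 was left out, 1 regulator rose and 1 hypertrophy gene fell. Of 20 genes of sulfation and glycosaminoglycan synthesis, Ugdh rose at 0.78 and 19 did not pass (camera adjusted p = 0.953; 1 rose adjusted over the list alone), with 1, 0, 1, 1, 0 and 0 higher and 0, 0, 1, 0, 0 and 0 lower with each library left out. The median and mean of that list were 0.02 and 0.11 while camera's direction was down. Cilp did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.0983, 0.124 and 0.119). Ugdh did not pass without WT replicates 1 and 2 (adjusted p of 0.0541 and 0.0863) or without A2ARKO replicates 2 and 3 (0.165 and 0.161).

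**Figure D3:**
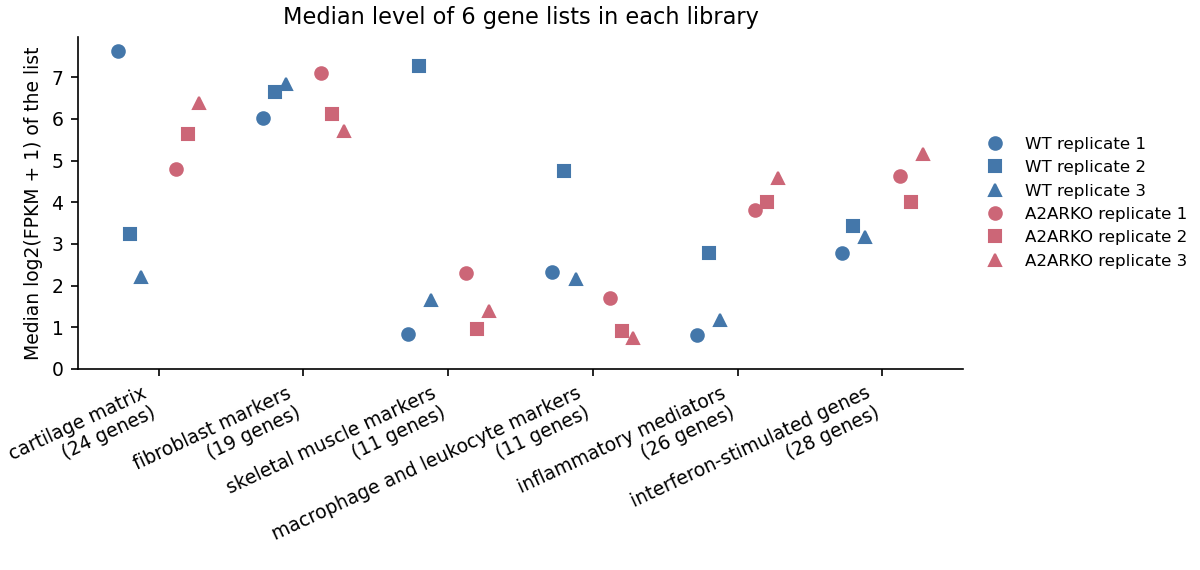
Median log2(FPKM + 1) of the tested members of 6 gene lists in each library; colour marks genotype and the marker shape the replicate number. WT replicate 1 has the highest cartilage matrix median (7.63), WT replicate 2 the highest skeletal muscle and leukocyte medians (7.27 and 4.75), and all 3 A2ARKO libraries lie above all 3 WT libraries for inflammatory mediators and interferon-stimulated genes.

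Growth factor pathways were not called as lists by camera with all libraries, and their members changed in both directions. An unadjusted limma p below 0.05 was reached by 10 of 26 Wnt and 18 of 35 TGF-beta and BMP genes, against 2863 of all 11595 tested genes. The adjusted p of fry's mixed test was 8.42e-05 for the Wnt list and 0.00135 for the TGF-beta and BMP list. Of 26 Wnt pathway genes, the secreted Wnt inhibitor gene Notum rose from 0.793 ± 0.287 to 5.92 ± 2.48 FPKM (SD, n = 3), 4 fell and 21 did not pass, and adjusted over the list alone 2 rose and 7 fell (camera adjusted p = 0.06895). Nkd1, Dkk3 and the receptor gene Fzd2 fell at log2 fold changes of -1.28, -1.08 and -0.86. Of the Wnt genes, 4, 3, 1, 1, 0 and 0 fell and 1, 0, 1, 1, 0 and 0 rose with each library left out in turn, and the list was called lower without WT replicate 2 (adjusted p = 0.0189) and without A2ARKO replicate 1 (0.02975). Of 35 genes of the TGF-beta and BMP pathway, Bmp6 rose at 0.96 and 34 did not pass (camera adjusted p = 0.953; adjusted over the list alone, 6 rose and 6 fell). The median of this list was -0.08 while its mean was 0.10 and camera's direction was up. Of these genes 2, 0, 6, 0, 0 and 0 rose and 2, 2, 2, 0, 0 and 0 fell with each library left out in turn. Notum did not pass without WT replicate 2 (adjusted p = 0.0553) or without A2ARKO replicates 2 and 3 (0.0746 and 0.0698). Bmp6 did not pass without WT replicates 1 and 2 (adjusted p of 0.06015 and 0.0653) or without A2ARKO replicates 1, 2 and 3 (0.123, 0.173 and 0.173).

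For genes reported in human osteoarthritic cartilage, the direction was mixed. Among 26 genes reported higher in disease, 4 rose, 1 fell and 21 did not pass, and adjusted over the list alone 4 rose and 3 fell. Camera did not call this list (adjusted p = 0.6497), while fry's directional test called it higher (adjusted p = 0.0178). The prostaglandin E synthase gene Ptges, S100a4 and the cytokine gene Lif were among those that rose, at log2 fold changes of 1.49, 1.34 and 0.81 (Lif was named after its value was seen), and the collagen gene Col6a3 fell at -0.87. Among 24 genes reported lower in disease, 6 rose, 2 fell and 16 did not pass, and adjusted over the list alone 9 rose and 3 fell. This list was higher in A2ARKO (camera adjusted p = 0.00669; adjusted p = 0.417 with an estimated correlation), with an adjusted p of 0.0687 without WT replicate 3. Angptl4, a regulator of lipoprotein lipase, rose from 9.32 ± 4.885 to 118 ± 14.97 FPKM (SD, n = 3), and Sod2, the vasoactive peptide gene Adm and Errfi1 rose at 1.95, 1.92 and 1.72. Of the 28 and 25 genes of these lists, 20 and 15 are also in another list. Angptl4 did not pass without A2ARKO replicate 2 (adjusted p = 0.0525). Of the former list 4, 3, 4, 1, 1 and 1 genes, and of the latter 10, 7, 6, 2, 0 and 1, rose with each library left out in turn, and 2, 2, 1, 0, 0 and 0 and 2, 1, 2, 0, 0 and 1 fell.

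Fibroblast markers fell as a list (median -0.49; camera adjusted p = 0.0221; adjusted p = 0.415 with an estimated correlation): 3 of 19 members fell, 1 rose, 15 did not pass, and adjusted over the list alone 6 fell and 1 rose. The matrix gene Dpt fell from 41.7 ± 15.95 to 8.18 ± 3.67 FPKM (SD, n = 3), Cd34 and Twist1 fell at log2 fold changes of -1.08 and -0.64, and S100a4 rose. The list's adjusted p was 0.0885 without WT replicate 3, and 1, 1, 1, 0, 0 and 0 members fell and 0, 0, 1, 0, 0 and 0 rose with each library left out in turn. Dpt did not pass without WT replicates 1 and 2 (adjusted p of 0.0535 and 0.0742) or without A2ARKO replicates 1, 2 and 3 (0.06398, 0.134 and 0.144). Tendon and ligament markers fell as a list with none of 6 members past the test (camera adjusted p = 0.0423; adjusted p = 0.375 with an estimated correlation; 2 fell adjusted over the list alone and 2 had an unadjusted limma p below 0.05), and the transcription factor genes Scx and Mkx had log2 fold changes of -0.89 and -0.74. Its adjusted p was 0.0687 without WT replicate 3 and 0.0554 without A2ARKO replicate 3, and 1, 1, 1, 0, 0 and 0 members fell with each library left out. Adipocyte markers rose as a list (camera adjusted p = 0.0126; adjusted p = 0.519 with an estimated correlation), with the adipogenic regulator gene Pparg higher at 0.83, 9 of 10 members not past the test and 2 adjusted over the list alone; the adjusted p was 0.0556 and 0.0504 without WT replicates 1 and 3. Pparg did not pass without WT replicates 2 and 3 (adjusted p of 0.0742 and 0.05335) or without A2ARKO replicates 1, 2 and 3 (0.05335, 0.1125 and 0.0948).

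Leukocyte markers fell as a list although none of 11 members passed (camera adjusted p = 0.00311; adjusted p = 0.519 with an estimated correlation; 0 adjusted over the list alone, 6 at an unadjusted limma p below 0.05). Lyz2 and the lysosomal gene Laptm5 had log2 fold changes of -3.84 and -2.42, and WT replicate 2 held the highest value of both. Without it the list median was -0.91; Laptm5 then fell at -1.49 and Cd14 and S100a8 rose at 0.85 and 1.20, the latter 2 named after their values were seen. None of 11 skeletal muscle markers passed (median -1.72; camera adjusted p = 0.06895; 0 adjusted over the list alone, 0 at an unadjusted limma p below 0.05). The troponin genes Tnni1 and Tnnt3 read 78.1 and 175 FPKM in WT replicate 2 and at most 1.15 and 5.79 in the other libraries. Without that library the muscle median was 0.225, and the list was called lower without WT replicate 1 (adjusted p = 0.00491), WT replicate 3 (0.0472) or A2ARKO replicate 1 (0.04801). None of the smooth muscle (9 tested), osteoclast (5) or sex-linked (5) markers passed, at camera adjusted p of 0.299, 0.176 and 0.189, and adjusted over the list alone 2 osteoclast markers fell and 0 of the others passed, where 0, 2 and 1 had an unadjusted limma p below 0.05. Without WT replicate 1 or 3, 1 osteoclast marker fell. The members with the smallest p were Smtn and Myh11, Ctsk and Itgb3, and Eif2s3y and Kdm5d, at log2 fold changes of -0.35, 1.25, -0.80, -0.87, -1.26 and -0.54. The sex of the pooled animals is not given in the sources used here. Xist, which is expressed in female cells and was named after its values were seen, was listed at 0 in WT replicate 3 and read 4.99 and 11.97 FPKM in WT replicates 1 and 2 and 15.2, 8.58 and 9.57 in the A2ARKO libraries. The Y-linked gene Eif2s3y read 10.98, 5.29 and 12.3 FPKM in the WT libraries and 1.45, 5.42 and 3.6 in the A2ARKO libraries, so these markers varied between the pools. From WT to A2ARKO the mean of Xist went from 5.65 to 11.1 FPKM and that of Eif2s3y from 9.53 to 3.49, with neither called. Whether the sex mix of the pools differs by genotype and bears on other genes was not tested. Lists of endothelial, erythroid, Schwann cell and neural, and keratinocyte markers had 3, 0, 4 and 2 tested members and were not tested as lists. Of 38 genomic neighbours of Adora2a, Gstt1 and Agpat3 rose at 1.42 and 0.72 and 36 did not pass (4 rose adjusted over the list alone; camera adjusted p = 0.0734), and the list was called higher without WT replicate 2 (adjusted p = 0.0421), with 3, 2, 2, 1, 0 and 0 members higher with each library left out.

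Camera at its preset correlation called 16 of the 34 lists, 12 higher and 4 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.375 and 2 lists had an unadjusted p below 0.05. Fry called 14 lists in its directional test, of which 11 matched camera's calls, and 25 in its mixed test. Its directional adjusted p was 0.0576 for interferon-stimulated and for cell cycle genes, and 0.053, 0.25 and 0.203 for fibroblast, leukocyte and adipocyte markers. Not called by camera but higher by fry were genes reported higher in human osteoarthritic cartilage (0.0178), adenosine and nucleotide handling (0.0482) and neighbours of Adora2a (0.0257). The remaining called members of lists with 5 calls, named after their values were seen, were Cd59a (complement), Pgam1 (glycolysis), Nfe2l2 (antioxidant), Mcm7 (cell cycle) and Hsp90aa1 (heat shock), which rose at log2 fold changes of 0.81, 0.83, 0.52, 0.74 and 0.67, and Fzd1 (Wnt), which fell at -0.57. With each library left out in turn, camera called 19, 18, 12, 20, 16 and 15 lists. Splits of the 6 libraries that mix the genotypes called 8 to 20 lists by camera at its preset correlation. The estimated correlation was 0.712 for interferon-stimulated, 0.728 for cell cycle, 0.615 for glycolysis and 0.318 for inflammatory genes. It was 0.095 for antioxidant and -0.033 for immediate early and heat shock genes. Where the members of a list correlate more than the preset, its preset p-value is too small.

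Genotype separated the libraries along the first principal component, which held 50% of the variance, while the second, with 30%, set WT replicate 1 apart from the others. Without WT replicate 1 the first component held 68.7%. The mean root-mean-square log2 distance was 0.614 within WT, 0.278 within A2ARKO and 0.671 between the groups. The median within-group SD of a gene was 0.192 in WT and 0.097 in A2ARKO, and 78.9% of genes had the larger SD in WT.

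**Figure D4:**
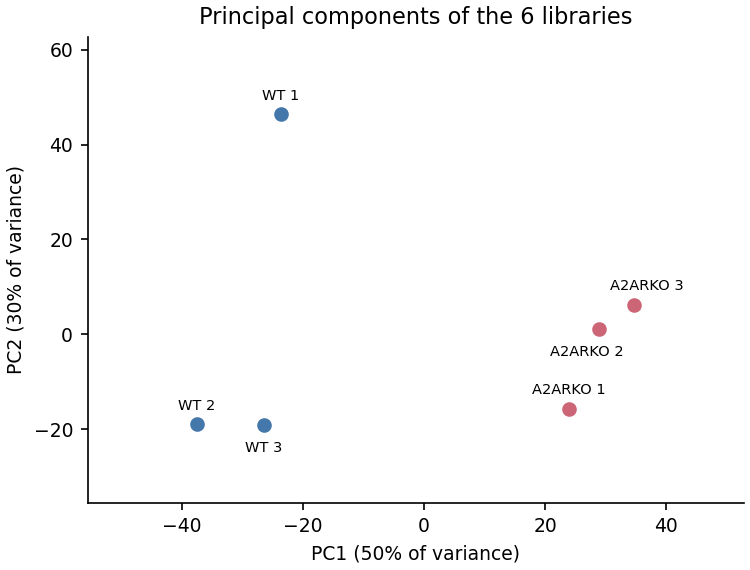
First and second principal components of the tested genes, 1 point per library, coloured by genotype and labelled with group and replicate number. The genotypes lie on opposite sides of the first component, and WT replicate 1 stands at 46.4 on the second, where the other 5 libraries lie between -19.15 and 6.25.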

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

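The voom fit and the fit without muscle and leukocyte genes and WT replicate 2 were chosen after the results were seen. No called gene changed sign under any fit. All 589 had no overlap between the groups. Leaving out a library or changing the pseudocount, filter or variance model therefore could not change their sign. The main count of 589 (384 higher, 205 lower) lay between 517 and 585 with pseudocounts of 0.1 and 5, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, robust eBayes and voom. It was 213 (143 higher, 70 lower) with no filter, where 26442 genes were tested, 348 (178 higher, 170 lower) after rescaling to the same sum, 327 (165 higher, 162 lower) when gene types were also left out, 1363 (817 higher, 546 lower) with array weights, whose estimation stopped before convergence, and 294 (199 higher, 95 lower) without muscle and leukocyte genes and WT replicate 2. For all but the first, the cause was not tested. The median of all genes moved from 0.002 to -0.098 with rescaling and to -0.107 when gene types were also left out. Other thresholds gave 1414 (864 higher, 550 lower) at adjusted p below 0.1, 62 (44 higher, 18 lower) below 0.01 and 253 (177 higher, 76 lower) with 1 log2 unit or more. With 1 library left out, fewer samples were fitted and the count ranged from 50 to 900 (39 to 568 higher, 11 to 362 lower), the Adora2a log2 fold change from -2.60 to -1.99, the number of lists from 12 to 20 and the share of the first component from 45.3% to 68.7%. Camera called 0 lists with an estimated correlation and 14 to 16 under the other alternatives, where the complement list, protease inhibitors list and tendon and ligament markers list had adjusted p of up to 0.0570, 0.0581 and 0.0719, and the odds ratio near Adora2a lay between 0.83 and 1.18. Same-numbered libraries deviated in opposite directions (correlations of -0.52, -0.33 and -0.39), which gives no sign of a pairing by number; with a replicate block limma called 2 (1 higher, 1 lower), with 2110 genes at an unadjusted p below 0.05, and Adora2a had -2.245 (adjusted p = 0.121), while 16 lists were called. The alternatives for raw counts were not run, since the values are FPKM. With 3 litters per genotype, changes of 0.5 log2 units were recovered in 26% of genes simulated above low levels and with equal spreads in both groups.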

Other observations

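The 5 lists in the next sentences and the tests of explanations, other than the planned Fisher's exact test of genes near Adora2a, were chosen after the results were seen, so these lists are not independent evidence of their direction. Acute-phase proteins, secreted in quantity during inflammation, were higher in 14 of 15 members (camera adjusted p = 5.75e-15; adjusted p = 0.0899 with an estimated correlation). Besides the Saa genes, haptoglobin (Hp) rose from 97.6 ± 38.2 to 906 ± 367 FPKM (SD, n = 3), the pentraxin gene Ptx3 from 209 ± 60.5 to 1038 ± 215 FPKM and Lbp from 17.5 ± 7.26 to 108 ± 43.65 FPKM. Hp did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.06398, 0.0521 and 0.0547). Ptx3 did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.06398, 0.0797 and 0.0749). Lbp did not pass without A2ARKO replicates 1, 2 and 3 (adjusted p of 0.06675, 0.121 and 0.103). With WT replicates 1, 2 and 3 and then A2ARKO replicates 1, 2 and 3 left out in turn, 13, 10, 11, 7, 3 and 6 members passed.

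Genes of the amino acid response, which responds to a shortage of amino acids, fell in 6 of 25 members (camera adjusted p = 2.49e-10; adjusted p = 0.247 with an estimated correlation). They were Trib3, Aldh1l2, Pycr1, the amino acid transporter gene Slc7a5, Atf5 and Eprs, and Atf5 fell from 215 ± 11.75 to 93.5 ± 12.8 FPKM (SD, n = 3). Aldh1l2 lies within 10 Mb of Adora2a. Of 20 imprinted growth genes, Cdkn1c, Meg3 and Grb10 fell at log2 fold changes of -1.88, -1.61 and -0.98 and Dio3 rose at 3.07 (camera adjusted p = 2.41e-06; adjusted p = 0.0899 with an estimated correlation). Of 18 elastic fibre genes Eln, Fbn2 and Ltbp4 fell and Efemp2 rose (camera adjusted p = 0.469), and of 17 circadian clock genes Dbp and Tef fell (adjusted p = 0.529). With each library left out in the same order, 8, 3, 8, 2, 1 and 1 amino acid response genes and 8, 2, 5, 1, 0 and 0 imprinted genes passed, and 4, 2, 7, 1, 0 and 0 elastic fibre and 3, 3, 2, 0, 0 and 1 clock genes. Atf5 did not pass without A2ARKO replicates 2 and 3 (adjusted p of 0.0843 and 0.0749). Gm15920, a processed pseudogene (mm10 chromosome 5, 130188395 to 130188796) whose reads are uncertain, fell from 22.35 ± 2.315 to 0.14 ± 0.05 FPKM, passed whichever library was left out, and was chosen after its values were seen.

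Inflammatory mediators were higher in A2ARKO in 16 of 26 members. More leukocytes in the A2ARKO cultures would raise their markers, but the median log2 fold change of 11 leukocyte markers was -1.89 (upper quartile -1.78), and -0.91 (upper quartile -0.82) without WT replicate 2, although Cd14 and S100a8, chosen after their values were seen, rose without that library; the abundant marker Lyz2 was lower in all 3 A2ARKO than in all 3 WT libraries. Scaling between libraries is argued against as the whole cause, since 14 of the 16 members still passed after rescaling to the same sum or leaving out gene types, and 15 after quantile normalization. A culture or harvest batch shared by the litters of a genotype cannot be told apart from genotype, since no batch is given and genotype itself also sets the mean root-mean-square log2 distances, which were 0.278 within A2ARKO, 0.614 within WT and 0.671 between the groups. An effect of the receptor's loss may account for the rise and stays open with it.

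Among markers reaching 1 FPKM in any library, WT replicate 2 was highest for 23 of 23 skeletal muscle and 17 of 17 leukocyte markers. None of these is in another list. A marker that reached 1 FPKM in that library alone is highest there by the filter. In at least 3 libraries, 11 muscle and 11 leukocyte markers reached it. For every library this held for 4 of 25 muscle and 3 of 18 leukocyte list genes. The library's most abundant muscle genes included Mylpf at 482 FPKM, against at most 7.98 elsewhere, with Tnnt3 at 175, Lyz2 at 1434 and Cd68 at 70.4 FPKM (Mylpf and Cd68 were chosen after their values were seen). A lower chondrocyte share raising all other cell types alike is argued against, because the median change of the muscle markers between WT replicates 1 and 2 exceeded that of the fibroblast markers, which was 0.13 (SD 0.86 over the markers), by 5.84 log2 units. Skeletal muscle and myeloid cells in that culture are candidate sources. The labels set this library apart by no group, so no biological difference was weighed against them.

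The real grouping called 589 genes with limma and 16 lists with camera. Among the 10 splits of the 6 libraries, only the real one called that many genes. The others called 0 by limma, with at most 1160 genes at an unadjusted p below 0.05. Each of them mixes the genotypes, so any difference between the genotypes widens the spread within its groups and lowers the calls. These 0 calls therefore cannot tell whether genotype or a shared batch separates the libraries. For lists, 3 splits called as many as the real one, itself included, and the others called 8 to 20 by camera. The number of lists called therefore did not set the real grouping apart. For either count, 10 splits are too few for a share under 0.05. Donor-strain sequence flanking Adora2a stays open for the genes within 10 Mb of it, since the interval of the odds ratio includes 1: 8 of 178 tested genes there were called against 564 of 11065 elsewhere (odds ratio 0.88, 95% interval 0.37 to 1.78, two-sided Fisher's exact p = 0.864). The 8 called genes there include Gstt1, Agpat3, Pfkl of the glycolysis list and Aldh1l2 of the amino acid response list. Strain differences beyond the widest window of 20 Mb were not tested, which leaves out Gm15920 and Gm9855. Gm9855, a processed pseudogene (mm10 chromosome 10, 42054113 to 42055306) chosen after its values were seen, fell from 3.19 ± 1.18 to 0.00667 ± 0.0115 FPKM.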
